A study of Mus musculus with 2 samples.

How the data were processed

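Total RNA from the left cerebral cortex of aged male mice was sequenced in 2 libraries, which the labels describe as biological replicates 1 and 2 of a single group. Per the labels, the mice were B6CASTF1/J, a first-generation hybrid of a B6 and a CAST parent strain, aged 18 to 20 months. Per the labels, RNA was purified with a column kit for animal tissue, 300 ng entered each library, and ERCC spike-ins from a profile for stranded, ribosomal-RNA-reduced libraries were added. The labels give both samples 1 donor identifier and separate biosample identifiers and do not say whether they came from separate animals. The spread between them may therefore be partly or wholly technical.

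Each library had 3 deposited tables. The gene table and the first transcript table have the column layout of RSEM and were derived from a transcriptome alignment, per the file headers and the deposited file lists. The second transcript table has the column layout of kallisto and was derived directly from 1 read file, per the deposited file lists. The assembly was mm10 and the annotation GENCODE M21, per the deposited file lists. The aligner, the tool versions, the quantifier settings and the use of strand in counting are not given in the sources used here.

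The deposited expected counts are the RSEM-layout estimates of reads per gene or transcript, and the deposited estimated counts of the second table play the same part there; neither is whole-numbered or normalized. The deposited TPM values are length-normalized abundances, scaled to the same total in each library over all listed features, which per the file headers include genes, spike-ins and, in the RSEM-layout tables, tRNA entries. The deposited posterior mean TPM and the bounds of its credibility interval come from the same tables, and the level of that interval is not given in the sources used here. The percent of a gene's TPM held by each transcript is also a deposited column. Values were estimated by dividing reads among transcripts, so near-identical copies and overlapping genes share reads and are called uncertain where named. The deposited tables were made on the reference genome, so CAST variants may also have lowered the counts of some genes by an amount that was not measured.

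Of 81881 rows in the gene table, 55536 matched a gene of the annotation (GRCm38, the assembly also called mm10) by identifier, 97 were spike-ins and 26248 were tRNA entries named only by a number. The second table was summed per gene, and 86 annotated genes had no entry in it. Where a symbol had more than 1 gene identifier, the identifier with the higher mean TPM was used. Coordinates are those of the annotation, on GRCm38. Annotated genes held 22827984 expected counts in replicate 1 and 29897486 in replicate 2.

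The second quantification assumed fragments of about 347 bases in replicate 1 and 345 in replicate 2, as calculated from its length columns. It assigned 0 reads to the 8617 transcripts shorter than 250 bases in either library, where the RSEM-layout tables held 35560 and 58931 expected counts, and 6526 and 9788 reads to the transcripts of 250 to 400 bases, where they held 1098592 and 1607375. Its values for small RNAs were therefore not used for any statement on level or direction.

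Expected counts were rounded to whole numbers. Scaling used the TMM factors of edgeR 4.0.16 in R 4.3.3, which were 1.02 and 0.984 for replicates 1 and 2. The log2 ratio of replicate 2 over replicate 1 was taken after adding 0.5 to each count and subtracting the log2 ratio of effective library sizes, 0.34. A 95% exact (Clopper-Pearson) interval of each ratio was calculated from its 2 counts. These intervals cover counting error only, since reads without molecular identifiers are not independent molecules. Spike-in scaling moved the median log2 ratio of all genes by -0.13 and deposited TPM by -0.15, so directions are read relative to matched genes. A gene is called higher or lower beyond counting error where its interval excludes 0 after TMM scaling. For intervals that end near 0, that call depends on the scaling.

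With 1 group of 2 libraries, no condition was compared and no p-value across genes is reported. A difference between the replicates describes these 2 libraries. Gene lists were judged by the percentile of their median log2 ratio among 10000 random lists of the same size, matched on mean TPM in 40 bins. A list outside the central 95% is said to lie above or below the range. Random lists were drawn from all annotated genes at a mean TPM of 1 or more, so noncoding classes that differ between the libraries could move the range. Only the glucocorticoid response list was also compared with nuclear protein-coding genes alone, where the range was -0.09 to 0.18. A list needed 3 or more members at a mean TPM of 1 or more. Of 2 genes in a pair, 1 was called higher where the deposited intervals did not overlap, in the same direction, in both libraries. A gene was called detected at a TPM of 1 or more in both libraries. Dispersion came from an intercept-only edgeR fit after filterByExpr. Correlations across genes used log2(TPM + 0.1), and genes are not independent replicates.

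The 40 gene lists (397 genes), the 18 pairs, the 20 genes examined for isoforms, the thresholds and the first set of alternatives were chosen before the data were examined. Named genes were, from each list, up to 4 with the highest mean TPM and up to 2 with the largest log2 ratio; up to 10 of the 20 most abundant nuclear protein-coding genes; the 10 largest ratios in each direction among protein-coding genes with a mean count of 100 or more; every pair; up to 10 of the 20 isoform genes, by largest disagreement between quantifications and largest share of the major isoform; and every sex check gene. Other genes are named with a statement that they were chosen after their values were seen. A few genes that the rule takes, and the pairs that contain them, are not reported here. Alternatives were DESeq2 1.42.0 size factors, spike-in scaling, deposited TPM, the second quantification, other pseudocounts, other minimum values and each replicate left out in turn.

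The steps were tested on simulated counts for 27480 genes with the means and library sizes of the real libraries. Of 200 genes changed by 1.5 on the log2 scale, 92.5% were recovered past 2-fold at a true coefficient of variation of 0.1 and 85.5% at 0.2, while 0.00821% and 1.90% of unchanged genes with a mean count of 100 or more passed 2-fold. In 50 simulated lists of 10 genes shifted by 1 on the log2 scale, 100% lay above the range. Of the unshifted lists, 6% lay outside it. Simulated genes varied independently, which members of a real list may not. Tables were handled with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots were drawn with matplotlib 3.10.9.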

Results

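Total RNA from the left cerebral cortex of male B6CASTF1/J mice aged 18 to 20 months was measured in 2 replicate libraries of a single group. The series holds no second condition, so its data describe which RNAs the aged cortex contained and how far the replicates differed. Replicate 1 held 22827984 expected counts over annotated genes and replicate 2 held 29897486. At a TPM of 1 or more, 16085 genes were detected in replicate 1, 15116 in replicate 2 and 14708 in both. Of those detected in both, 12868 were nuclear protein-coding genes, out of 22015 annotated. Values below are the mean of the 2 libraries ± SD (n = 2) unless a replicate is named.

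Snap25, a SNARE protein of synaptic vesicle fusion (ENSMUSG00000027273.13, chromosome 2, 136713453 to 136782428), had the highest mean among nuclear protein-coding genes, 1434 ± 35.7 TPM. Ptgds, the prostaglandin D synthase, followed at 1173 ± 26.2 TPM and Camk2a, a synaptic protein kinase of excitatory neurons, at 1112 ± 87.3 TPM. The chaperone Hspa8 stood at 1100.0 ± 45.4 TPM, the glycolytic enzymes Gapdh at 1098 ± 61.0 and Aldoa at 1094 ± 27.3, and the ferritin heavy chain Fth1 at 1039 ± 8.08. Actb and Eef1a1 reached 986 ± 54.0 and 981 ± 49.3 TPM. Snurf, which overlaps Snrpn, was listed at 1029 ± 18.9 TPM but at 0 in the second quantification, so its level is uncertain. The 20 most abundant genes held 4.32% of all nuclear protein-coding TPM and the top 100 held 13.1%.

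RNA classes other than messenger RNA took a large part of the total. The 7SL RNA genes Rn7s1 and Rn7s2, which encode the RNA of the signal recognition particle and share reads as near-identical copies, were each listed at 133417 ± 7134 TPM. The 7SK RNA Rn7sk, a regulator of transcription elongation, was at 62525 ± 1060 TPM. Of the mitochondrial ribosomal RNAs, mt-Rnr2 was at 42492 ± 1856 TPM and mt-Rnr1 at 28755 in replicate 1 and 29462 in replicate 2. The mitochondrial messenger RNA mt-Co1 was at 6234 ± 157 TPM. Nuclear protein-coding genes held 45.5 ± 1.54% of TPM and 80.6 ± 0.23% of expected counts. The class misc_RNA, which includes the 7SL and 7SK RNAs, held 33.0 ± 1.32% of TPM and 4.56 ± 0.37% of counts, because TPM divides by length and these RNAs are short. In the second quantification nuclear protein-coding genes held 75.3% of TPM. It assigned few reads to transcripts of 250 to 400 bases, the range that holds the 7SL and 7SK RNAs: 6526 and 9788 in replicates 1 and 2, against 1098592 and 1607375 expected counts. Of genes annotated as long intergenic noncoding RNA, Gm26917 was listed at 11093 ± 779 TPM and the nuclear noncoding RNA Malat1 at 5052 ± 1834. For Gm26917 this is the annotated class only, and whether its reads come from a long noncoding RNA was not tested.

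The cell type and region lists ranked the RNA as neuronal cortex with glia. Pan-neuronal genes had a median of 215 TPM in replicate 1 and 199 in replicate 2, and excitatory neuron genes 144 and 138. Upper cortical layer genes stood at 54.8 and 56.6 TPM, with Lamp5 at 106 ± 9.16. Deep layer genes stood at 23.3 and 23.1 TPM, led by Tbr1, a transcription factor of layer 6 neurons, at 52.5 ± 0.40. Astrocyte genes had medians of 52.6 and 53.0 TPM, with the glutamate transporter Slc1a2 at 698 ± 60.0 and Gfap at 55.6 ± 4.85. Inhibitory neuron genes had medians of 29.6 and 31.0 TPM, and the neuropeptide gene Sst reached 187 ± 5.37. Oligodendrocyte genes stood at 25.5 and 26.0 TPM, with the myelin gene Mbp at 389 ± 14.8.

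Lists of other cell types had lower medians, which do not measure cell numbers. Microglial genes had medians of 10.5 and 12.2 TPM, with Csf1r at 26.3 ± 0.43. Endothelial genes stood at 7.72 and 6.59 TPM and oligodendrocyte precursor genes at 5.92 in both replicates. The erythroid list had 5 of 7 members detected, with Hbb-bs at 150.5 ± 7.52 TPM and the near-identical copies Hba-a1 and Hba-a2 at 151 ± 1.65 and 132 ± 1.27. Lists for neighbouring tissue differed. All 10 striatal genes and 6 of 8 thalamic genes were detected, with medians of 11.9 and 23.4 TPM and of 4.39 and 3.57 TPM in replicates 1 and 2, whereas 3 of 8 cerebellar genes, 4 of 8 hippocampal genes, 1 of 7 hypothalamic genes and 2 of 5 olfactory bulb genes were detected. Of 8 lymphocyte genes, Cd4 alone was detected, and of 11 ependymal and choroid plexus genes 3 were, led by Ttr at 13.4 ± 5.32 TPM. Of the 40 lists, 32 had a median of 1 TPM or more. Among the lists of state, all 12 immediate early genes were detected, with Arc at 195 ± 21.7 TPM and Egr1 at 143 ± 10.2, while 2 of 8 proliferation and neurogenesis genes were detected, Dcx at 9.24 ± 2.45 and Sox11 at 7.24 ± 1.46.

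**Figure D1:**
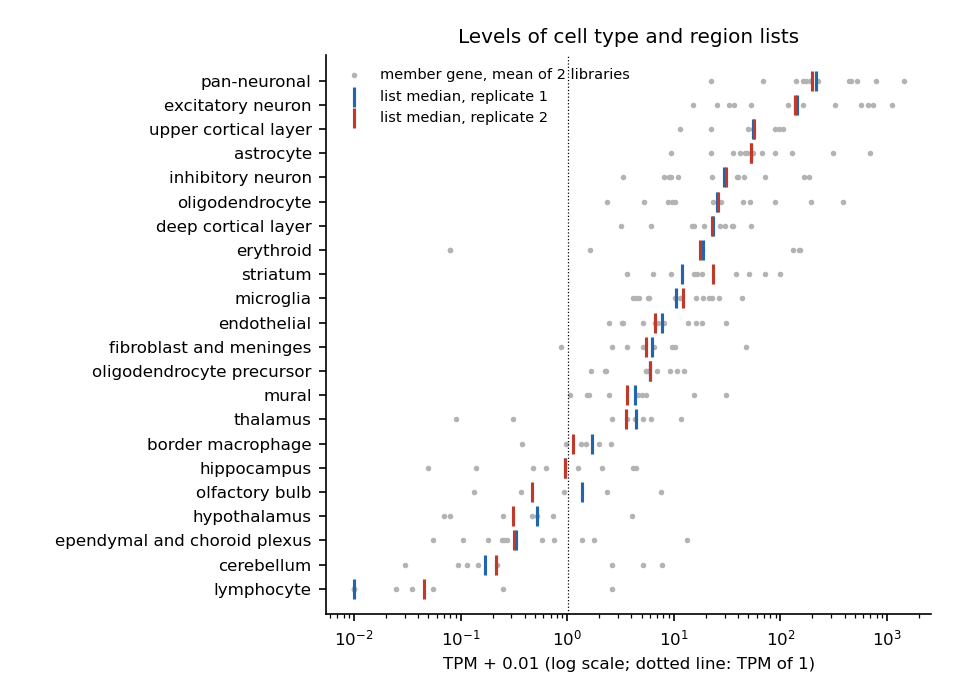
Levels of 22 cell type and region lists on a logarithmic axis of TPM + 0.01; grey points are member genes (mean of the 2 libraries) and the vertical ticks are the list medians in replicate 1 (blue) and replicate 2 (red). Pan-neuronal genes had the highest medians (215 and 199 TPM), and the striatum list has separated ticks at 11.9 and 23.4 TPM.

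Comparing related genes within each library, 17 of the 18 fixed pairs were called different, with the first gene higher in 16. The vesicular glutamate transporter of cortical neurons, Slc17a7, exceeded Slc17a6, which predominates in thalamus and brainstem, by 5.61 ± 0.12 on the log2 scale (48.9-fold). The potassium-chloride cotransporter Slc12a5, which keeps chloride low in mature neurons, exceeded Slc12a2 by 4.11 ± 0.05 (17.3-fold). The sodium channel genes Scn2a and Scn8a exceeded the developmentally early Scn3a by 3.16 ± 0.04 and 2.70 ± 0.31. Syt1 exceeded Syt2 by 4.21 ± 0.0016, Vamp2 exceeded Vamp1 by 3.19 ± 0.16, and Cux2 exceeded Foxp2 by 3.89 ± 0.33. The interneuron markers ranked Sst above Vip (3.04 ± 0.05) and above Pvalb, whose log2 ratio to Sst was -2.21 ± 0.10. Other pairs called were Slc1a2 over Slc1a3 (2.43 ± 0.12), Camk2a over Camk2b (2.03 ± 0.07), Gad1 over Gad2 (1.88 ± 0.14), Apoe over Clu (1.32 ± 0.01) and Gria2 over Gria1 (1.12 ± 0.18). Grin2a and Grin2b, NMDA receptor subunits, were not called: their log2 ratio was -0.16 ± 0.15 and their intervals overlapped in replicate 1 but not in replicate 2. In counts, where a call needed a mean over 3 times the SD, Grin2b was called higher, with a log2 ratio of -0.82 ± 0.06. The Apoe excess over Clu was 2.49-fold in TPM but 1.40-fold in the second quantification and 1.52-fold in counts, and the Syt1 excess over Syt2 was 18.5-fold in TPM and 27.8-fold in the second quantification. In counts, which are not divided by length, the Slc1a2 excess over Slc1a3 was 12.3-fold against 5.41-fold in TPM, that of Gad1 over Gad2 1.76-fold against 3.69-fold, that of Sst over Vip 3.52-fold against 8.20-fold and that of Slc12a5 over Slc12a2 11.4-fold against 17.3-fold.

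Isoform use was examined in 9544 genes with a TPM of 5 or more in both libraries and 2 or more annotated transcripts. The major isoform was the same transcript in both replicates in 89.5% of these genes, and it held a median of 61.9% of the gene's TPM. App-201 made up 91.8 ± 0.3% of the amyloid precursor gene App and Snap25-201 84.9 ± 1.2% of Snap25. Mapt-204 held 71.4 ± 0.9% of the tau gene Mapt. The leading transcript of Camk2a held 61.2 ± 0.7%. Both quantifications led with the same transcript in these 4 genes.

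For other genes the leading isoform or its share depended on the quantification. Snrpn-201 held 96.2 ± 0.2% of Snrpn in the RSEM-layout table and 0.1 ± 0.1% in the second table, where Snrpn-202 held 99.9 ± 0.1%. Apoe-209 held 87.8 ± 0.4% of Apoe in the first and was listed at 0 in the second, where Apoe-205 held 94.6%. The share of Clu-201 was 96.4 ± 0.8% in the first and 50.8 ± 0.9% in the second. Mbp-211 held 68.9 ± 1.0% of the myelin basic protein gene Mbp in the first and 37.3 ± 2.5% in the second, and the leading transcript of Dlg4, a scaffold protein of excitatory synapses, 54.6 ± 3.2% and 28.8 ± 0.3%. Over all 9544 genes, the tables named the same major isoform in 74.4% in replicate 1 and 76.2% in replicate 2, and all 4 estimates named the same transcript in 67.5% (6441 genes). Between quantifications, log2 TPM correlated across genes at r = 0.757 and 0.772 (rho = 0.886 and 0.899) in replicates 1 and 2. Features at a TPM of 1 or more in either table entered, including small RNAs with no usable value in the second. Across transcripts r was 0.358 and 0.380, so statements on single transcripts are less firm than those on genes.

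Replicate against replicate is the contrast the design holds. Genes of the striatum, the nucleus that lies under the cortex, were higher in replicate 2. The dopamine receptor Drd2 (ENSMUSG00000032259.8, chromosome 9, 49340627 to 49408177) had 76 counts in replicate 1 and 541 in replicate 2, a log2 ratio of 2.48 (95% counting interval 2.14 to 2.85). The adenosine receptor Adora2a (ENSMUSG00000020178.6, chromosome 10, 75316877 to 75334784) had 109 and 613 counts, a ratio of 2.14 (1.85 to 2.46). The orphan receptor Gpr6 differed by 1.55 (1.10 to 2.05). Rxrg, a retinoid receptor, Lrrc10b and Syndig1l differed by 1.79, 1.80 and 1.60 in the same direction.

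Genes lower in replicate 2 were of other kinds. Hif3a, a hypoxia-inducible factor, had 308 and 122 counts (-1.68, interval -1.99 to -1.37). The clock-controlled repressor Ciart had 164 and 98 counts (-1.08, interval -1.46 to -0.72). Gm21887 and Mid1, neighbours at the distal end of chromosome X (169685199 to 170019281 together), had ratios of -2.15 and -1.52; these genes lie at a boundary with repeated sequence shared by X and Y, so their counts are uncertain. Tmc4 (-1.13), Dok3 (-1.13), Col24a1 (-1.06), Tnfrsf25 (-1.04) and Pagr1a (231 and 146 counts) completed the 10. The deposited TPM intervals of replicates 1 and 2 overlapped for Pagr1a (5.53 to 26.6 and 3.63 to 20.8) and Col24a1 (1.79 to 3.26 and 0.834 to 2.21). These genes are therefore uncertain, although the second quantification gave ratios of -1.27 and -1.05. For Gm14288 and Gm14440 the 2 quantifications differed in sign, so no direction is given. Gm20388, Gm28539 and a second Myl12b gene identifier were higher in replicate 2 in both quantifications, but by amounts over 0.5 apart on the log2 scale, so no size is given. Gm14288, for example, had 380 and 0 counts in the RSEM-layout table but a ratio of 0.07 in the second.

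Among 12348 genes with a mean count of 100 or more, 31 were higher and 88 lower in replicate 2 by at least 2-fold. Of the 88, 66 carried the biotype TEC, which marks features still awaiting experimental evidence; among 11647 nuclear protein-coding genes 22 were higher and 10 lower. Past 2-fold in both quantifications were 18 higher and 7 lower protein-coding genes, and 9 of the 18 belonged to the striatum list. Agreement was otherwise close, with r = 0.985 and rho = 0.987 across 14708 genes, and 97.6% of nuclear protein-coding genes lay within 0.5 of equality on the log2 scale. The chi-square statistic between the libraries was 13.3 times its degrees of freedom over 17965 genes, a value to which noise in dividing reads among transcripts also adds. The biological coefficient of variation was 0.116 over 17210 genes and 0.084 over 14186 nuclear protein-coding genes. On the simulated counts, which included changed genes, the same fit gave 0.130 for a true value of 0.1 and 0.213 for 0.2. The value of 0.116 may therefore be too high. The SD of the centred log2 ratio of spike-ins was 0.096 over 24 spike-ins with a mean count of 100 or more, against a median of 0.194 (central 95% 0.127 to 0.425) in genes matched on count. The robust SD, which outlying features move less, was 0.121 in spike-ins and lay inside the range of matched genes (median 0.158, central 95% 0.0896 to 0.248). At a mean count of 500 or more the robust SD of spike-ins, 0.0532, lay below the range of genes matched there (0.0589 to 0.226).

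**Figure D2:**
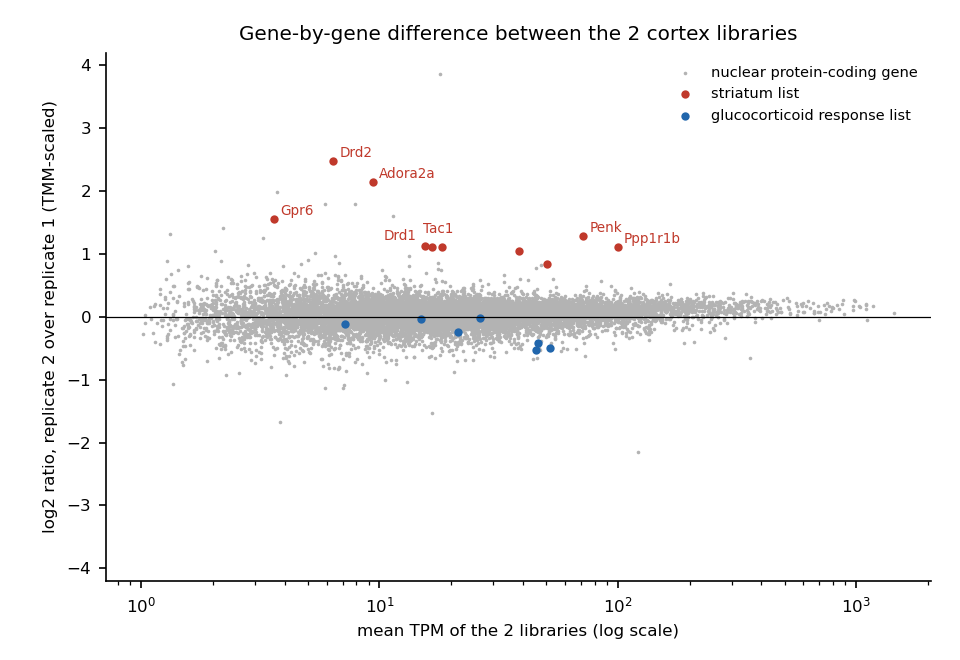
Log2 ratio of replicate 2 over replicate 1 against mean TPM (logarithmic axis) for 11631 nuclear protein-coding genes with a mean TPM of 1 or more and a mean count of 100 or more; 3 genes with 0 counts in 1 library lie beyond the axis. Red points are the 10 genes of the striatum list (7 labelled), all above 0.8, and blue points the 7 genes of the glucocorticoid response list, all below 0.

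Of 40 lists, 35 had enough expressed members to be compared between the replicates, and 5 lay above and 6 below the range of matched random lists. By chance 1.75 would lie outside if genes varied independently. Members of a list may vary together and some lists share members, so more could lie outside by chance. The striatum list stood farthest out, with a median log2 ratio of 1.11 (range of random lists -0.09 to 0.16), 2.16-fold, and all 10 members were higher in replicate 2 beyond counting error. Ppp1r1b, the dopamine-regulated phosphatase inhibitor DARPP-32, stood at 66.1 and 134 TPM in replicates 1 and 2, and Penk, the enkephalin precursor, at 45.8 and 97.3. Drd1 (chosen after its value was seen) and Tac1, which mark the direct output pathway of the striatum, differed by 1.12 (0.94 to 1.31) and 1.11 (0.82 to 1.41). The neuropeptide list had a median of 0.33 (range -0.08 to 0.18), with Npy at 0.33, Sst at 0.19 and Cck at 0.12. It shares Penk and Tac1 with the striatum list, and its median without them was 0.28. Whether RNA of its other members also came from striatal cells was not tested. The deep cortical layer list had a median of 0.23 (range -0.10 to 0.16), and of its 10 members 7 were higher and 0 lower beyond counting error. Bcl11b and Foxp2, which striatal projection neurons also express, stood at 0.39 and 0.46, Rprm at 0.21 (0.07 to 0.36), Crym at 0.24 (0.09 to 0.38) and Tbr1 at 0.06. Tle4 and Fezf2, chosen after their values were seen, stood at 0.25 (0.15 to 0.36) and -0.08 (-0.25 to 0.09). Oligodendrocyte genes had a median of 0.22 (range -0.05 to 0.17): 9 of 12 were higher beyond counting error, including Cnp (0.35) and Opalin (0.89).

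The list for glial reactivity and antigen presentation had a median of 0.20 (range -0.10 to 0.16), and its members moved apart. The class II genes H2-Aa and H2-Ab1, which present peptides to T cells, had ratios of 1.05 (0.32 to 1.87) and 1.11 (0.33 to 2.00) on counts of 21 and 56, and 18 and 50. B2m, the light chain of class I molecules, had a ratio of -0.18 (-0.33 to -0.04). Lysosomal Ctsd and the apolipoprotein Apod stood at 0.21 and 0.16.

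Below the range lay a list of structural and regulatory noncoding RNAs, with a median of -0.48 (range 0.03 to 0.20). Malat1 (ENSMUSG00000092341.3, chromosome 19, 5795690 to 5802672), a nuclear noncoding RNA, had 6348 TPM in replicate 1 and 3755 in replicate 2, and the imprinted Meg3 differed by -0.74 (-0.75 to -0.72). The small RNAs Rn7sk, Rmrp and Rpph1 of the same list had ratios of 0.10, 0.24 and 0.19, so its members went both ways. The glucocorticoid response list had a median of -0.24 (range -0.10 to 0.19), and 4 of its 7 members were lower beyond counting error, among them Sgk1 at -0.53 (-0.64 to -0.42), Tsc22d3 at -0.49 (-0.60 to -0.39) and Zbtb16 at -0.41 (-0.49 to -0.34). The circadian clock list had a median of -0.17 (range -0.06 to 0.15); the repressor Per1 stood at -0.32 (-0.38 to -0.25) and Nr1d1 at -0.27 (-0.36 to -0.18). Of its 12 members 8 were lower and 2 higher beyond counting error, among the latter Npas2 (chosen after its value was seen) at 0.22 (0.12 to 0.32). Ionotropic glutamate receptor genes had a median of -0.09 (range -0.02 to 0.16), with Grin2b at -0.25 and Gria2 at -0.08 but Gria1 at 0.12. Upper cortical layer genes had a median of -0.13 (range -0.07 to 0.20), with Cux1 at -0.32 and Cux2 at -0.13. Of the 7 members 4 were lower and 2 higher beyond counting error, and the list lay inside the range in deposited TPM. The 4 Y-linked genes had a median of -0.26 (range -0.17 to 0.21).

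The other 24 lists lay inside the range. They included excitatory neuron genes (0.04), astrocyte genes (0.12), microglial genes (0.14), endothelial genes (-0.09), immediate early genes (0.07) and nuclear oxidative phosphorylation genes (0.20). Excitatory Slc17a7 stood at 0.09 and Camk2a at -0.05, and astrocytic Slc1a3 at 0.11. The heat shock list lay inside the range at -0.04, although its near-identical copies Hspa1a and Hspa1b stood at -0.64 and -0.60. Some of these calls depended on the setting. In deposited TPM the heat shock list (-0.24) and the list of imprinted genes expressed from the maternal allele (-0.35) lay below the range. In the second quantification the microglial (0.19), nuclear oxidative phosphorylation (0.25), inhibitory neuron (0.20) and hippocampal (0.42) lists lay above it. The lists overlap in places and describe 2 libraries, with 1 library on each side of every ratio.

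**Figure D3:**
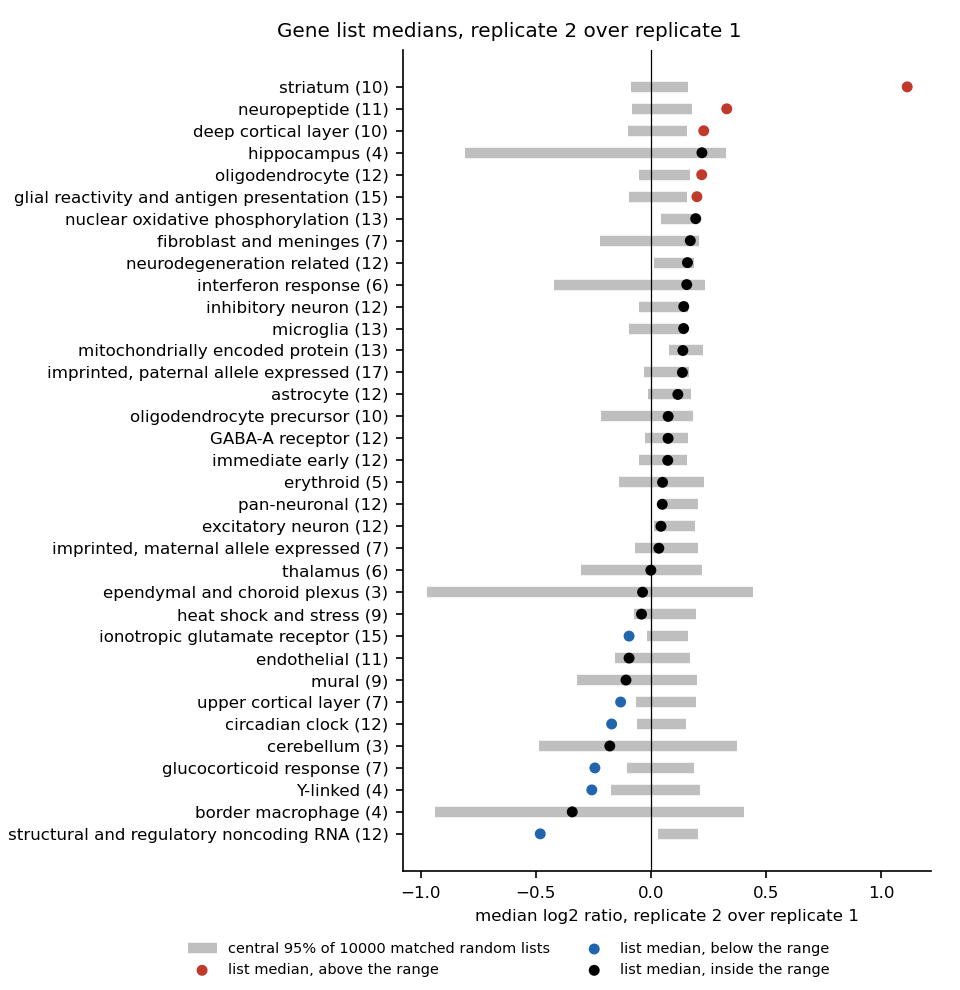
Median log2 ratio of replicate 2 over replicate 1 for 35 gene lists (points; number of members in brackets) with the central 95% of 10000 random lists matched on mean TPM (grey bars). The striatum list at 1.11 stands farthest above its bar and the structural and regulatory noncoding RNA list at -0.48 farthest below.

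By annotated class, noncoding features lying mainly within genes stood lower in replicate 2. Of 409 TEC features with a mean count of 50 or more, 396 were lower, with a median log2 ratio of -0.95, and of 35 sense_intronic transcripts 34 were lower, with a median of -0.92. Long intergenic noncoding RNAs had a median of -0.19 over 186 genes and antisense transcripts -0.18 over 96. Kcnq1ot1, an imprinted noncoding RNA transcribed within an intron, differed by -1.14 (-1.20 to -1.08). Nuclear protein-coding genes had a median of 0.05 over 12618 genes, which was -0.07 with spike-in scaling and -0.09 in deposited TPM, so no direction is given for them. Mitochondrial protein-coding genes had a median of 0.14 over 13, which was 0.01 with spike-in scaling and 0.005 in deposited TPM, so no direction is given for them either. All 21 small nuclear RNA genes were higher in replicate 2, with a median of 0.43, and 32 of 35 small nucleolar and Cajal body RNAs, with a median of 0.31; their copies share reads and are uncertain. The second quantification gave medians of -0.92 for TEC features, while it holds no usable values for the small RNAs.

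**Figure D4:**
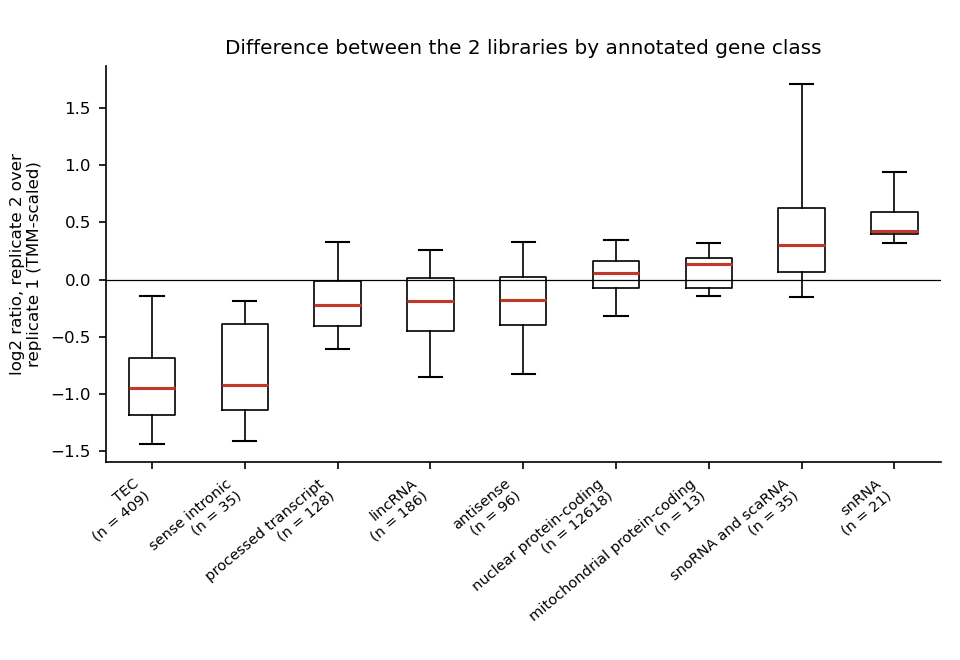
Log2 ratio of replicate 2 over replicate 1 by annotated gene class, for genes with a mean count of 50 or more; red lines are medians, boxes the middle 50% and whiskers reach from 5% to 95% of genes. TEC and sense_intronic features, with medians of -0.95 and -0.92, lie below the nuclear protein-coding genes at 0.05.

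The Y-linked genes and Xist matched the male label of both samples. Eif2s3y stood at 28.7 ± 7.82 TPM, Ddx3y at 21.2 ± 0.40, Uty at 10.9 ± 2.60 and Kdm5d at 7.58 ± 1.07. Xist, the RNA of X inactivation in females, had 4 and 6 counts, and Tsix 3 and 4. Between the replicates, Eif2s3y, Kdm5d and Uty had ratios of -0.34, -0.33 and -0.18, and Ddx3y 0.21.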

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

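The tests of the second lists, of strand and of retained introns were chosen after the first lists and classes had been seen but before their own values were; the tests of Drd1 and Tac1 and of scaling were chosen only after the result was seen, although the list medians in deposited TPM and the second quantification that the scaling test of striatal genes uses had been chosen before the data were examined.

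The tRNA entries of the gene table, which the comparisons did not use, held 3.9 expected counts in replicate 2, over the limit of 3 that a count of 0 allows; they are 26248 entries named only by a number, of which 4 were above 0.

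Striatal genes were higher in replicate 2, with a list median of 1.11 on the log2 scale. Scaling did not account for it: 1 factor for all genes moves matched random lists alike, and the lower of the medians in deposited TPM and in the second quantification was 1.05, above the matched random lists (upper bound 0.04). Induction of the indirect output pathway alone would leave Drd1 and Tac1 of the direct pathway unchanged. Both were higher, with a lower counting bound of 0.82, which argues against that pathway alone. Both belong to the striatum list that showed the pattern, so this was not an independent test. Drd2 and Adora2a of the indirect pathway differed further (2.48 and 2.14), so a partial role was not excluded. More striatal tissue in the sample of replicate 2 may explain the pattern: a second list of 10 striatal genes, including Pde7b, Mme and Zfp503, had a median of 0.45 against an upper bound of 0.17. No label describes the dissection, and cortex also expresses such genes (Ptpn5, the most abundant of the second list at 80.6 TPM, had a ratio of 0.24), so this stays a hypothesis.

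Noncoding features lying mainly within genes were lower in replicate 2, with a TEC median of -0.95. Of the 4 other settings, spike-in scaling and size factors apply 1 factor to all genes, so they cannot move TEC features relative to other genes. In deposited TPM and in the second quantification the TEC medians were -1.03 and -0.92, so scaling did not account for it. Less genomic DNA in replicate 2 would lower features on both strands and between genes alike. Yet the 312 features on the sense strand of a protein-coding gene lay -0.39 from the 97 others (bootstrap interval -0.62 to -0.29). Of these others, 78 lay between genes, still at -0.68, and only 19 were antisense, at -0.37 (bootstrap interval -0.84 to -0.10). The difference is thus mainly one of sense against between genes, and the use of strand in counting is not given. A contribution of DNA stays open. Less unspliced nuclear RNA in replicate 2 is a candidate explanation. Within 3443 genes, retained-intron transcripts differed from protein-coding transcripts by -0.59 (bootstrap interval -0.61 to -0.57), and were relatively lower in 3069 genes. These counts came from the RSEM-layout transcript table only. Less DNA could lower intron-containing transcripts too, so the comparison cannot separate unspliced RNA from DNA. In lists not fixed beforehand, 10 nuclear long noncoding RNAs, including Malat1, had a median of -0.66 (lower bound -0.01), all lower beyond counting error. The 5 exported ones stood at -0.09, inside the range (-0.15 to 0.21). Less DNA would lower both alike, which argues against DNA for these RNAs, not for TEC features. Not all nuclear RNA was lower: 21 of 21 small nuclear RNA genes and 32 of 35 small nucleolar and Cajal body RNAs were higher. Whether RNA extraction, RNA quality or the tissue set the difference between the libraries was not tested.

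Glucocorticoid response genes were lower in replicate 2, with a list median of -0.24. The shift in unspliced RNA did not account for it as far as gene structure captures that shift: after removing the trend on intron length, exon length and expression, which took out 5.06% of the variance, the median was -0.22 (lower bound of random lists -0.11). Lower glucocorticoid receptor activity in the animal or tissue of replicate 2 could be involved, since a second list of 13 induced genes, including Ddit4, Nfkbia and Arrdc2, had a median of -0.19 (lower bound -0.09). Time of day of collection, which also sets clock genes such as Per1, is not in the labels and cannot be separated from it here.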

How the results depend on the processing

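The alternatives of spike-in scaling and of shared genes for lists, the omission of classes or striatal genes, and protein-coding genes alone for the correlation were chosen after seeing the data. Genes detected, pairs called and lists at 1 TPM or more stayed within 1.5 times under every alternative run; leaving out either replicate gave 15116 to 16085 genes, 17 to 18 pairs and 32 to 33 lists. Nuclear protein-coding genes held 44.4 to 46.6% of TPM with either replicate left out, 80.6% of expected counts, 75.3% of TPM in the second quantification and 72.3% without the small RNA classes, since TPM divides by length and the second quantification omits short transcripts. The correlation of replicates was 0.966 with no filter. DESeq2's median gene-wise dispersion gave a coefficient of variation of 0.030. Of genes past 2-fold there were 113 higher and 559 lower at a mean count of 20 or more, 8 and 3 at 500 or more, 10 lower among nuclear protein-coding genes, 17 lower without TEC and sense_intronic features and 228 lower in the second quantification; apart from the gene sets tested, the cause was not tested. The share of lower genes among those past 2-fold was 73.9% with TMM, 83.8% with spike-in scaling and 82.8% in deposited TPM. Of the 11 lists outside the range, the noncoding RNA list holds small RNAs with no usable value in the second quantification and stayed below in deposited TPM; of the other 10 lists, 9 stayed on the same side in both deposited TPM and the second quantification (spike-in scaling and size factors move lists and random lists alike and cannot change a side), and the second quantification put 9 lists above the range; the cause was not tested. Spike-in SD was 0.210 at a mean count of 20 or more, against 0.318 (central 95% 0.215 to 1.32) in matched genes, and the robust SD, 0.166, lay inside its range (0.132 to 0.307); at 500 or more both were below theirs, SD 0.0717 (0.0888 to 0.246) and robust SD 0.0532 (0.0589 to 0.226). Major isoforms matched between replicates in 86.8% of genes at a TPM of 1 or more, 92.1% at 20 or more and 87.5% in the second quantification. The mean correlation between quantifications was 0.882 with no filter, 0.874 with a pseudocount of 1 and 0.629 with 0.01 across genes, and 0.605, 0.595 and 0.191 across transcripts; the cause was not tested. No called pair and none of these 10 lists changed direction; Grin2a against Grin2b, not called, changed sign in the second quantification. No paired analysis was possible because there is 1 group, and ratios between the replicates have no value with 1 left out. Genes under about 100 counts are limited by counting error.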

Other observations

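The genes in the next sentences were chosen after their values were seen. A list of class I antigen presentation genes was put together after the data were examined, so its place among random lists is not a test. It had a median log2 ratio of -0.76 over 6 expressed members, below the range of matched random lists (-0.32 to 0.22). Of the 6 members, 5 were lower in replicate 2 beyond counting error. Of these, H2-K1 had 396 and 273 counts (-0.88, interval -1.11 to -0.65) and H2-D1 552 and 451 (-0.63, interval -0.82 to -0.45), while the class II chaperone Cd74 had 65 and 167 counts (interval of the log2 ratio 0.60 to 1.45). These genes are highly variable between mouse strains and similar to each other, so their counts are uncertain. Ttr, a thyroid hormone carrier made by the choroid plexus, stood at 155 and 385 counts (0.97, interval 0.70 to 1.25), and Clic6 of the same list at 21 and 57 counts (1.08, interval 0.35 to 1.89), while Kl and Foxj1 had ratios of -0.04. Dlk1, an imprinted gene, had 56 and 191 counts (1.42, interval 0.99 to 1.88), whereas Meg3, Rian and Mirg of the same imprinted region of chromosome 12 had ratios of -0.74, -0.34 and -0.56.

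Eomes, a marker of olfactory bulb and of newborn neurons, had 35 and 3 counts and Th, the rate-limiting enzyme of dopamine synthesis, 33 and 16. The mitochondrial gene mt-Co2 had a ratio of 1.25 in the RSEM-layout table and 0.63 in the second, beside nuclear copies that share its reads. Gapdh stood at 1098 TPM in the first quantification and at 3680 and 4056 TPM in the second.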
